A study of Mus musculus with 8 samples.

How the data were processed

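Transcripts in mouse paw tissue were measured by RNA sequencing in 8 libraries, 4 from males and 4 from females of the inbred strain C57BL/6J. According to the labels, all mice had received 0.1 µg prolactin (PRL) per injection into the sole of the paw for 12 days, 1 injection per day. The labels' protocols state that about 500 ng total RNA entered a stranded poly(A)-selecting kit, in which dUTP marks the second strand, and that single-end reads of 50 bp were sequenced on an Illumina instrument. Per the submitters' processing notes, bcl2fastq, TopHat2 and HTSeq were used with the mouse build mm9. Versions, the annotation and the strand setting of the counting are not given in the sources used here.

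The authors deposited 1 file per library with whole-number read counts per gene symbol and no normalization. Each file held 22609 gene symbols plus the counter's own summary lines. Those lines name no gene and stayed out of library sizes and tests. Reads in no feature made up 18 to 21.1% of the uniquely placed reads, and ambiguous reads 0.2 to 0.23%. The line for alignments that were not unique held 17427599 to 26386679, or 45.2 to 48.7% of all lines together. Whether that line counts reads or alignments is not known. Reads shared by near-identical gene copies are missing from the counts. Values for members of multigene families (the serpins, defensins, aldo-keto reductases and Skint genes named here) are therefore uncertain, to an extent that was not measured. The genome build at hand differed from mm9, so gene symbols are given as deposited and no coordinates are printed.

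The counts in genes summed to between 16753528 and 24993744 per library. Ratios of summed counts were corrected for the summed library sizes of each sex, scaled by TMM. Their counting intervals (95%, exact conditional binomial) and floors (3 counts over the group) cover counting error only. Replicate libraries were compared by a chi-square test over genes with at least 20 counts. The statistic per degree of freedom was 13.2 or more for all pairs of the same sex, far above sampling noise. None of these pairs thus looked like repeat sequencing of 1 library, and every library was treated as its own replicate. The test cannot show that each library came from a different animal.

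Female was compared with male with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (14790 of 22609), libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit and glmQLFTest, robust) was run with sex as the sole term. Log2 fold changes are female over male with their standard error (SE). For single genes the SE was derived from the test, as the size of the log2 fold change over the square root of its F statistic. P-values were adjusted by Benjamini-Hochberg over all tested genes, with calls at an adjusted p under 0.05. Means ± SD are in CPM, counts scaled by TMM to a common library size. Of 44 gene lists, 2 held sex-chromosome genes and served as the check of the labels. The 41 others with at least 4 tested genes were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 41 lists; the last held 2 tested genes and was not tested. A list score is the mean log2 CPM of its tested members.

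Groups, tests, lists and the rule for named genes were fixed before the data were examined. Named were the sex-chromosome genes, and up to 12 called genes per direction with the largest fold change among those with a mean CPM of at least 2 and no overlap between the sexes. Where fewer than 5 passed, genes with the smallest p were added up to 5 and are said not to pass. Prlr, Stat5a, Stat5b, Socs2, Cish and Esr1 were named whatever their test gave, as were up to 4 members of each called list and up to 2 called members of each other list. Ocm, Cartpt, Jak2, Skint8 and the further genes named in the closing part lie outside that rule and were chosen after their values were seen. The same holds for Awat1, Awat2, Dgat2l6, Gsdmc, Hbegf, Krt6a, Krt6b, Krt16 and Krt17. Some genes that the rule names are not reported here.

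The alternatives were other size factors (those of DESeq2, upper quartile), DESeq2 1.42.0, and limma-voom with and without library weights. Further ones were no filter or a CPM of at least 2 in at least 4 libraries, a non-robust fit, the replicate number as a block, a surrogate variable from sva 3.50.0, and the mean log CPM of the fast muscle genes as a covariate. Each library was also left out in turn, other thresholds were set, and lists were tested with an estimated correlation and with fry. Data were also simulated for the female against male comparison with known fold changes (14669 genes tested). On these the test called 62 of 62 genes changed 4-fold, 20 of 65 changed 2-fold and 3 of 66 changed 1.5-fold, and 2 unchanged genes. Simulated genes were independent, had the trended dispersion and carried no difference in muscle content. The shares therefore need not hold for the real libraries, where edgeR did not call Skint5 at a log2 fold change of 3.34 (SE 0.50). Figures were drawn with Python and matplotlib.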

Results

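Polyadenylated RNA from paw tissue was sequenced in 4 male and 4 female C57BL/6J mice, all labelled as given prolactin, the pituitary hormone best known for lactation, at 0.1 µg per daily intraplantar injection for 12 days. The labels' protocol also lists PBS and shorter arms, which were not analysed here, so the values describe the sexes under prolactin with no untreated background. Counts in genes summed to 20416187, 19666013, 18183645 and 20356106 in male replicates 1 to 4. They summed to 16753528, 21676252, 22599702 and 24993744 in female replicates 1 to 4. The question the design poses is whether the transcripts of the prolactin-treated paw differ between females and males, in a series about sex and lasting pain.

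Sex-chromosome transcripts parted the libraries as labelled in 8 of 8 cases. Xist, the RNA that coats the inactive X chromosome, stood at 1712 ± 152 CPM in females and 1.59 ± 0.242 CPM in males (SD, n = 4 each). The Y-linked genes tested were Ddx3y (an RNA helicase), Eif2s3y (a translation initiation factor subunit), and Uty and Kdm5d (members of histone demethylase families). They had 516 to 2882 counts in each male library and 0 to 3 in each female library. Scaled to library size, Ddx3y counts were 1466 times higher in males (95% counting interval 744 to 3396), and Kdm5d counts 579 times (248 to 1785). All 4 were called higher in males by the edgeR quasi-likelihood test, with adjusted p from 7.73e-08 for Ddx3y to 3.77e-05 for Kdm5d, and Xist was called higher in females (adjusted p = 6.28e-08).

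Among X-linked genes that escape inactivation, Kdm6a, a histone H3K27 demethylase, was higher in females, at 98.8 ± 9.34 CPM against 51 ± 4.43 CPM (log2 fold change 0.95, SE 0.09, edgeR adjusted p = 0.00844). Of the 5 tested members of this list, Xist included, edgeR called 2 over all genes and 4 when adjusted over the list alone. Kdm5c had a log2 fold change of 0.48 (SE 0.08, edgeR adjusted p = 0.128), Eif2s3x 0.65 (SE 0.12, adjusted p = 0.175) and Ddx3x 0.14 (SE 0.10, adjusted p = 0.925). Over all genes DESeq2 also called Kdm5c (adjusted p = 0.000518) and Eif2s3x (0.00143). The call of Kdm6a was lost without male replicate 3 or male replicate 4, where its adjusted p reached 0.0672 at most.

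Beyond the sex chromosomes, females had more transcript of a pair of clade B serpins (intracellular protease inhibitors), a steroid-metabolising enzyme and a receptor kinase. Serpinb6e stood at 21 ± 6.04 CPM in females and 0.246 ± 0.0927 CPM in males (SD, n = 4 each). The ratio of its counts, scaled to library size, was 85.6-fold, with a counting interval of 54.7 to 143 (log2 fold change 6.38, SE 0.32, edgeR adjusted p = 5.14e-05). Its relative Serpinb1c stood at 7.69 ± 1.44 against 2.23 ± 0.372 CPM (log2 fold change 1.78, SE 0.19, adjusted p = 0.0167). Akr1c21, an aldo-keto reductase that acts as a hydroxysteroid dehydrogenase, stood at 74.2 ± 18.3 against 20.7 ± 3.48 CPM (1.84, SE 0.20, adjusted p = 0.0167). Adrbk2, a kinase that desensitises G protein-coupled receptors, stood at 67.5 ± 13.7 against 28.3 ± 2.95 CPM (1.25, SE 0.15, adjusted p = 0.0304).

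Males had more transcript of an antimicrobial peptide, of an enzyme of retinol metabolism and of a calcium-binding protein. Defb8, a beta-defensin, had 493 to 1310 counts in each male library and 1 count in each female library. Scaled to library size, the ratio was 1186 with a counting interval of 463 to 4353 (edgeR adjusted p = 5.14e-05). Adh7, an alcohol dehydrogenase that oxidises retinol, stood at 126 ± 17.5 CPM in males and 63.6 ± 7.33 CPM in females (log2 fold change -0.99, SE 0.12, adjusted p = 0.0304). Ocm, which encodes the parvalbumin-type protein oncomodulin, was low in both sexes, with 24 to 30 counts per male and 3 to 4 per female library (-2.99, SE 0.27, adjusted p = 0.00502).

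**Figure D1:**
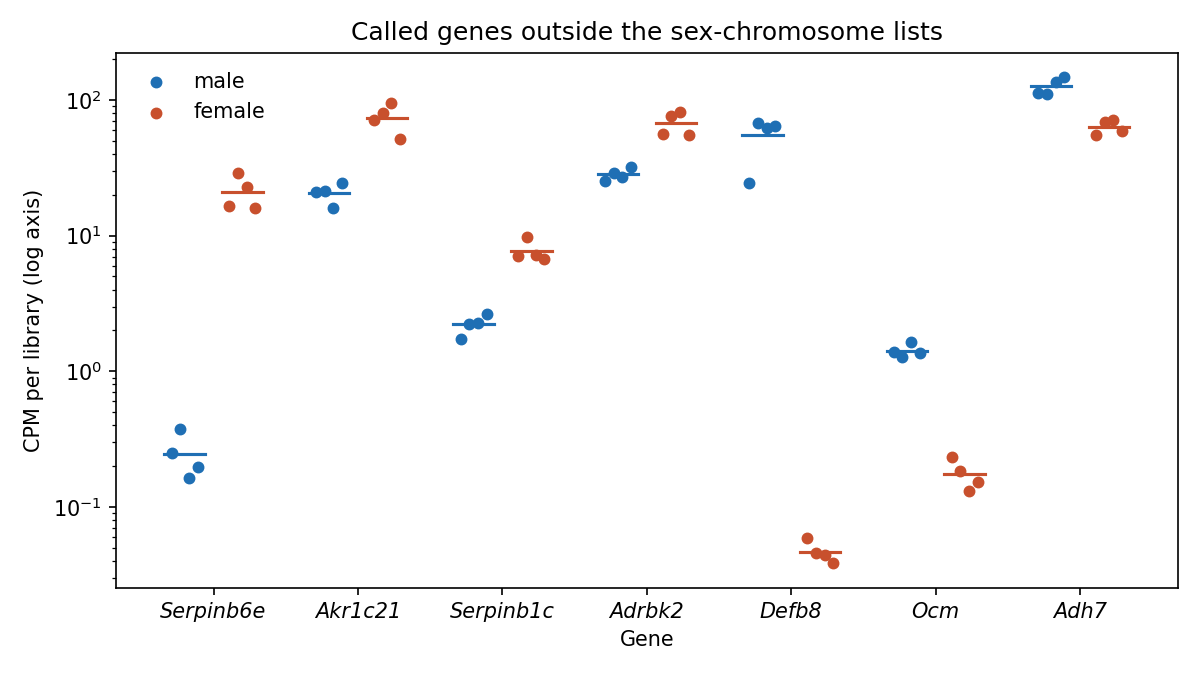
TMM-scaled CPM (log axis) of 7 of the 8 called genes outside the sex-chromosome lists, with 1 point per library (4 male, 4 female) and a line at each group's mean. The male and female points of each gene do not overlap; Defb8 lies at a mean of 54.7 CPM in males and 0.047 CPM in females.

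In all, edgeR called 14 of 14790 genes, 6 higher in females and 8 higher in males, of which 8 lay outside the sex-chromosome lists (4 in each direction). An unadjusted p under 0.05 was reached by 966 genes, against 740 expected by chance, and the libraries of the sexes did not overlap for 700 genes (4.7%, against 2.9% by chance). The chance values carry no spread, and the counts were not computed for other groupings of the libraries, so neither excess was tested. DESeq2 called 54 genes higher in females and 57 higher in males, and limma-voom 7 and 9, each with all 14 edgeR calls among them. Skint5, of a family expressed in skin and thymus epithelium, did not pass in edgeR (adjusted p = 0.0968). It stood at 7.7 ± 3.78 CPM in females and 0.76 ± 0.476 CPM in males. Hacl1, a peroxisomal enzyme of fatty acid alpha-oxidation (log2 fold change -1.12, SE 0.15, edgeR adjusted p = 0.0544), and Fam81a (-0.78, SE 0.11, edgeR adjusted p = 0.0783) did not pass there either. Skint5, Hacl1 and Fam81a were all called by DESeq2 (adjusted p = 3.33e-09, 1.86e-08 and 1.1e-06).

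With 1 library fewer, Serpinb6e, Defb8, Ocm, Xist and the 4 Y-linked genes remained called whichever library was left out. Adh7 lost its call without any of the 8 libraries, Adrbk2 without any except female replicate 4, Akr1c21 without any except female replicates 3 and 4, and Serpinb1c without any of the males or without female replicate 1. Their adjusted p then reached at most 0.162, 0.162, 0.0965 and 0.102, in that order, while their log2 fold changes stayed within -1.06 to -0.91, 1.15 to 1.33, 1.70 to 1.98 and 1.64 to 1.88. The number of genes called higher in females fell from 6 to 3 without male replicate 1, and to 2 without male replicate 3 or without male replicate 4. Of the 8 calls outside the sex-chromosome lists, 3 remained without male replicate 2, 3 or 4 or female replicate 1, 4 without male replicate 1 or female replicate 2, 5 without female replicate 3 and 7 without female replicate 4. Without female replicate 3, which held little muscle transcript, and with a muscle covariate, a fit chosen after seeing the data, 16 genes outside those lists were called, 7 of the 8 among them.

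Neither the receptor of the injected hormone nor its signalling genes passed the test between the sexes. Prlr stood at 38.4 ± 12.3 CPM in females and 30.9 ± 2.24 CPM in males (SD, n = 4 each), a log2 fold change of 0.31 with an SE of 0.21 (edgeR adjusted p = 0.906). Stat5a, a transcription factor that the receptor activates, stood at 36.6 ± 4.04 against 38.6 ± 2.33 CPM, and Stat5b at 71.5 ± 30.5 against 84.5 ± 35.5 CPM (adjusted p = 0.999 for both). The feedback inhibitors Socs2 and Cish, which STAT5 induces, had log2 fold changes of 0.22 (SE 0.16, adjusted p = 0.920) and 0.00 (SE 0.26, unadjusted p = 0.985). Of the 14 prolactin receptor and JAK-STAT5 genes, 8 lay above 0 and 6 below, and 0 were called by edgeR, DESeq2 or limma-voom. In edgeR 0 passed when adjusted over the list alone, and 1, Jak2, had an unadjusted p under 0.05. Their mean log2 fold change was 0.03 (camera adjusted p = 0.695). The estrogen receptor gene Esr1 had a log2 fold change of -0.16 (SE 0.50, adjusted p = 0.999).

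Circadian clock genes, the feedback loop that times daily rhythms, were called higher in females as a list by camera. Of its 14 tested members 11 lay above 0, with a mean log2 fold change of 0.24 (camera adjusted p = 0.00104; adjusted p = 0.946 with an estimated correlation). None was called over all genes by edgeR, and 2 were when adjusted over the list alone, Hlf and Per1. Hlf, a PAR bZIP transcription factor, stood at 64.7 ± 12 against 34.8 ± 2.59 CPM (log2 fold change 0.90, SE 0.14, adjusted p = 0.106 over all genes). Per1, a repressor of the loop, stood at 90.7 ± 6.94 against 56.9 ± 7.74 CPM (0.67, SE 0.11, adjusted p = 0.128 over all genes). DESeq2 called both. Cry2 (0.50, SE 0.17) and Arntl (0.21, SE 0.10) did not pass, with adjusted p of 0.650 and 0.778.

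**Figure D2:**
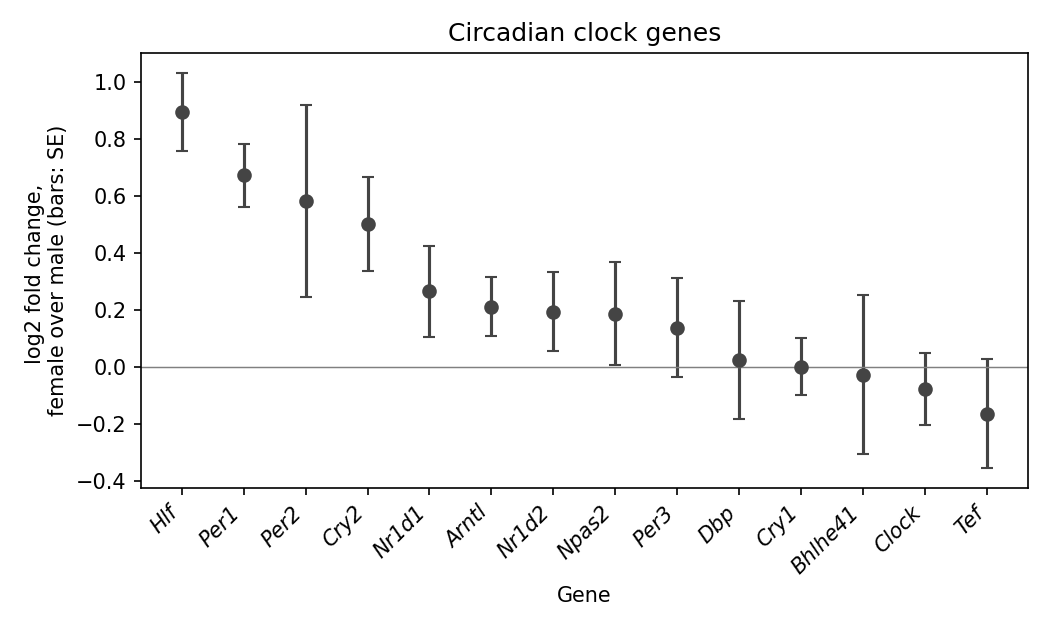
Log2 fold change, female over male, of the 14 tested circadian clock genes, with bars for the standard error derived from the edgeR F statistic. Hlf (0.90) and Per1 (0.67) lie highest and Tef (-0.16) lowest, and 11 of the 14 points lie above 0.

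Lists of skin lipid and stressed epidermis genes were called lower in females. Of 13 sebaceous and surface lipid genes 9 lay below 0 (mean log2 fold change -0.19, camera adjusted p = 0.0058; adjusted p = 0.946 with an estimated correlation). With no filter the mean was -0.11 (camera adjusted p = 0.0157). None was called over all genes by edgeR and 2 were when adjusted over the list alone. Fa2h, which encodes a fatty acid hydroxylase, stood at 128 ± 14.1 CPM in females and 228 ± 44.2 CPM in males (-0.83, SE 0.16, adjusted p = 0.179 over all genes). Elovl3, a fatty acid elongase gene, stood at 58.1 ± 7.17 and 99.1 ± 18.4 CPM (-0.77, SE 0.15, adjusted p = 0.205 over all genes). Over all genes DESeq2 called Fa2h (adjusted p = 0.00021) and Elovl3 (0.00172), while limma-voom called 0 members of the list, with or without library weights. Elovl4 (-0.24, SE 0.16) and Scd3 (-0.33, SE 0.23) did not pass. The 4 members above 0 were Dgat2l6 (0.22, SE 0.34), Awat2 (0.19, SE 0.26), Awat1 (0.18, SE 0.19) and Gsdmc (0.003, SE 0.41). Of 16 wound and stress keratinocyte genes 13 lay below 0 (mean -0.21, camera adjusted p = 0.0105; adjusted p = 0.946 with an estimated correlation), and none was called, adjusted over all genes or adjusted over the list alone. Its members of smallest p were the cornified envelope genes Sprr1b (-0.66, SE 0.20), Lce3c (-0.59, SE 0.19) and Sprr2d (-0.58, SE 0.28) and the beta-defensin gene Defb14 (-0.47, SE 0.26). The 3 members above 0 were Krt6b (0.34, SE 1.13), Hbegf (0.30, SE 0.27) and Krt6a (0.08, SE 0.36). The keratin genes Krt16 (-0.42, SE 0.66) and Krt17 (-0.002, SE 0.19) lay below 0 by less than their SE. General keratinocyte markers, not called (14 of 23 below 0, camera adjusted p = 0.138), had scores of -0.26, 0.22, 0.3 and -0.35 in female replicates 1 to 4, where the stress list had -0.49, 0.18, 0.46 and -0.46. In male replicate 2 the scores were -0.19 and -0.6. With the muscle covariate the mean of the stress list was -0.39 (camera adjusted p = 7.26e-06). The sebaceous call was lost without male replicate 4 (mean -0.12, adjusted p = 0.0535) or female replicate 4 (-0.11, 0.246), and its mean was -0.30 without female replicate 3. The keratinocyte call was lost without male replicate 1 (-0.12, 0.072), male replicate 4 (-0.16, 0.0633), female replicate 1 (-0.09, 0.249) or female replicate 4 (-0.10, 0.281). Its mean was -0.34 without male replicate 2 and -0.42 without female replicate 3.

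Of 16 cholesterol synthesis genes 11 lay below 0, with a mean log2 fold change of -0.11, and the list was called lower in females (camera adjusted p = 0.0395; adjusted p = 0.946 with an estimated correlation). None passed over all genes or adjusted over the list alone. Its members of smallest p were Sc4mol (-0.44, SE 0.14), Lss (-0.41, SE 0.14) and Cyp51 (-0.39, SE 0.16). With the muscle covariate the mean was -0.20 (camera adjusted p = 7.26e-06). When genes that track the muscle score were removed the mean was -0.12 and the call was lost (adjusted p = 0.0937). The call was also lost without male replicate 4 (mean -0.06, adjusted p = 0.242), female replicate 1 (-0.05, 0.460) or female replicate 4 (-0.06, 0.535), and the mean was -0.23 without female replicate 3.

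Muscle transcripts varied more between libraries than between the sexes. The mean log2 CPM of the fast skeletal muscle genes was 0.74 in female replicate 3 and 5.03 to 10.08 in the other 7 libraries. The first principal component, with 59.2% of the variance, placed female replicate 3 at one end (-84.2) and male replicate 2, the library with the most muscle transcript, at the other (59.8). Of the 20 fast muscle genes 19 lay below 0 (mean log2 fold change -0.48, camera adjusted p = 0.0322; adjusted p = 0.946 with an estimated correlation). No member was called, and the myosin gene Myh2 (-1.16, SE 1.52), Mybpc2 (-0.66, SE 1.34), Pgam2 (-0.67, SE 1.42) and Tmod4 (-0.58, SE 1.29) had SEs above their fold changes. The fast muscle mean was -0.94 with the replicate number as a block (camera adjusted p = 0.0147) and -0.29 with a surrogate variable (0.00283). Of 18 mitochondrial respiratory chain genes 18 lay below 0, with a mean log2 fold change of -0.17 (camera adjusted p = 0.0105; adjusted p = 0.946 with an estimated correlation). None was called, adjusted over all genes or adjusted over the list alone, and those of smallest p were Cox6c (-0.23, SE 0.09), Cox7b (-0.16, SE 0.08), Cox5a (-0.30, SE 0.16) and Uqcrc1 (-0.25, SE 0.18). Without male replicate 2 the mean of the fast muscle genes was 0.83 and that of the mitochondrial genes 0.04, and without female replicate 3 those means were -0.07 and -0.09, with no call of either list in these cases. With the muscle score as a covariate the mitochondrial mean was -0.06 (camera adjusted p = 0.355), and with a surrogate variable it was -0.08 (0.152), without a call in either. The list stayed called without the genes that track the muscle score (-0.17, adjusted p = 0.0458), and with the covariate when female replicate 3 was also left out (-0.13, adjusted p = 0.00678).

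**Figure D3:**
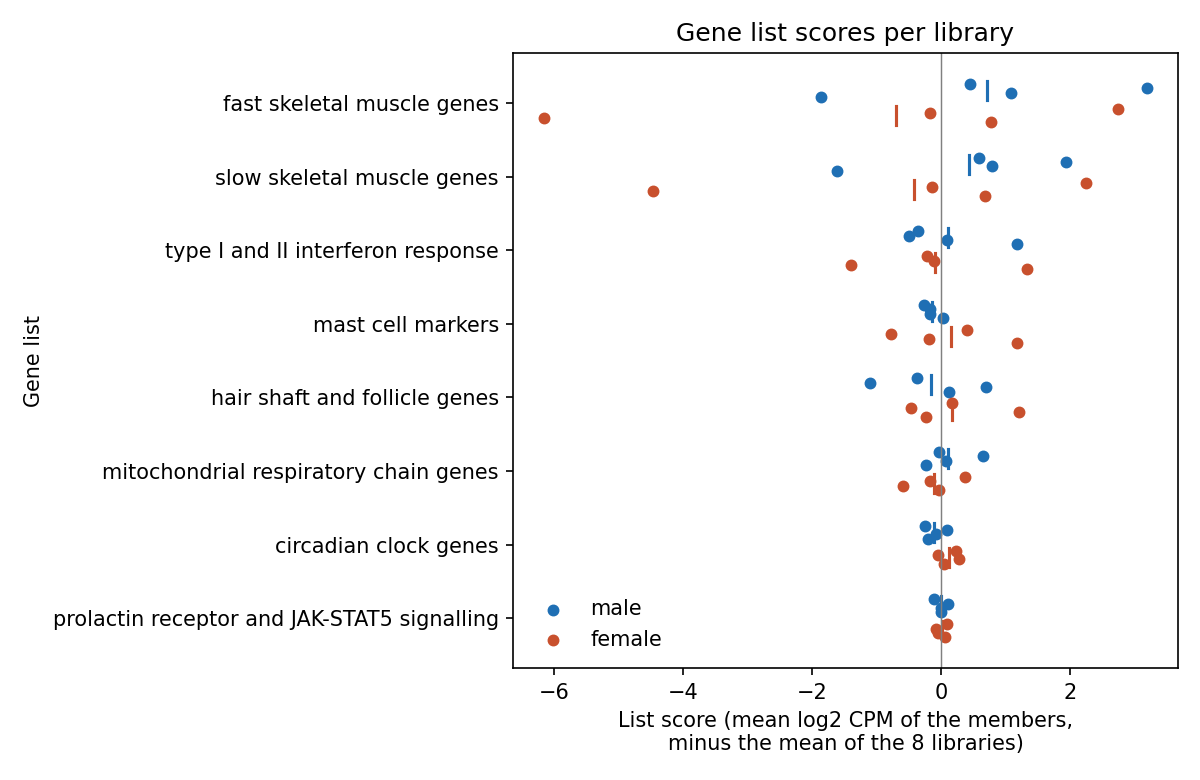
Score of 8 gene lists in each library, as the mean log2 CPM of the members minus the mean of the 8 libraries, with 1 point per library and a line at each group's mean. Fast muscle scores run from -6.16 in female replicate 3 to 3.19 in male replicate 2, while prolactin pathway scores lie between -0.12 and 0.11.

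The other 35 lists were not called. Nociceptor and sensory ion channels had a mean log2 fold change of 0.06 (6 of 9 above 0, camera adjusted p = 0.751). Interferon response genes had -0.02 (11 of 23 above 0, adjusted p = 0.556) and macrophage markers -0.02 (8 of 19 above 0, adjusted p = 0.205). Inflammatory cytokines and chemokines had a mean of 0.02 with 12 of 22 above 0, while the camera statistic pointed the other way (adjusted p = 0.882). Of 12 slow muscle genes 6 lay above 0 (adjusted p = 0.572). Lists just short of the threshold lay in both directions. Mast cell markers lay above 0 in 12 of 12 cases (mean 0.50, camera adjusted p = 0.0608), hair shaft and follicle genes in 23 of 24 (mean 0.37, adjusted p = 0.0582) and sex steroid genes in 5 of 9 (adjusted p = 0.0583). Complement components lay below 0 in 10 of 14 (mean -0.16, adjusted p = 0.0582). With an estimated correlation the adjusted p was 0.946 for each. Mast cell scores were 0.39, -0.78, -0.19 and 1.17 in female replicates 1 to 4, against -0.27 to 0.03 in males. Hair scores were highest in female replicate 3 (1.2) and lowest in male replicate 2 (-1.1), and complement scores ran from -0.71 to 0.63 in females. Across the 587 tested genes of the lists outside the sex chromosomes, edgeR called 0, with 36 at an unadjusted p under 0.05, DESeq2 called 8 and limma-voom 0, or 1 with library weights.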

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

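In 192 comparisons of 4 libraries of the same sex (library measures, named genes and list scores), 6 had a library whose gap to the nearest other was large against the range of the 4, where chance gives about 1 in 20. Defb8 in male replicate 1 stood at 4.62 log2 CPM, against 5.96 to 6.09 in the other males. Uty in male replicate 4 stood at 4.67 log2 CPM, against 5.07 to 5.12. Serpinb1c in female replicate 2 stood at 3.31 log2 CPM, against 2.77 to 2.86. Stat5b in male replicate 2, the library with the most muscle transcript, stood at 7.1 log2 CPM, against 5.99 to 6.18, and the glycolysis score of the same library at 0.36, against -0.07 to 0. Fa2h in male replicate 1 stood at 7.35 log2 CPM, against 7.89 to 8.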

How the results depend on the processing

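The fit without female replicate 3 and with the muscle covariate, and the fit without the 504 genes that track the muscle score (correlation above 0.9 in size), were chosen after seeing the data. Of the 14 called genes, Xist, the 4 Y-linked genes and Serpinb6e kept their call in 21 of 21 alternatives, and no called gene changed sign in any. Genes called higher in females (6) and in males (8) became 54 and 57 with DESeq2, and 7 and 9 with limma-voom. Those higher in females became 10 with library weights in limma-voom, 3 at an adjusted p under 0.01, and 12 without female replicate 3 and with the muscle covariate. Leaving out 1 library each gave 2 to 7 genes higher in females and 6 to 10 higher in males, with fewer samples in each fit. Defb8 lost its call only with library weights (adjusted p = 0.202), and Adh7 also with upper-quartile scaling.

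Lists called higher in females (1) became 4 with DESeq2 size factors, 5 with upper-quartile scaling, 4 with no filter, 2 with the stricter filter, 3 with a surrogate variable, 3 with the muscle covariate, and 4 with that covariate and without female replicate 3. Leaving out 1 library each gave 2 to 6 lists higher in females and 3 to 9 higher in males, and removing the genes that track muscle gave 3 higher in males. With an estimated correlation or with fry, 0 lists were called in either direction. The mean log2 fold change of the fast muscle list ran from -1.911 to 0.828 over the left-out libraries, and was -0.066 without female replicate 3, where camera pointed the other way; that of the mitochondrial list ran from -0.363 to 0.038, above 0 without male replicate 2. The mitochondrial list also lost its call with a surrogate variable, with the muscle covariate and without male replicate 2 or female replicate 3, and kept it without the genes that track muscle and with the covariate but without female replicate 3. The cause of the other changes was not tested.

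The labels do not say that the numbers 1 to 4 pair the samples. Deviations from the mean of each sex correlated at -0.31, -0.17, -0.09 and -0.27 between libraries of the same number. Such deviations largely follow muscle content, so they cannot show whether libraries of the same number shared a batch. With the replicate number as a block, 2 genes were called higher in females and 5 in males, and 4 lists higher in females. Depth limits genes near the floor, such as Ocm and Cartpt.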

Other observations

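The tests of the fast muscle pattern and the choice of the genes in the next paragraph came after the results were seen; the other tests were set before their results.

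Cartpt, which encodes a neuropeptide precursor, had 55, 63, 187 and 29 counts in female replicates 1 to 4 and 0 in all 4 males. Over all genes it was called by DESeq2 (adjusted p = 1.34e-09) and by limma-voom (0.0464) but not by edgeR (adjusted p = 0.205), with an edgeR range of 0.103 to 0.933 over the alternatives. The steroid enzyme gene Akr1c18 had a log2 fold change of 1.06 (SE 0.24, edgeR adjusted p = 0.363), and passed when adjusted over its list of 9 sex steroid genes alone (adjusted p = 0.0202). Penk, the enkephalin precursor gene, had -0.56 (SE 0.13, edgeR adjusted p = 0.320 over all genes and 0.0386 over its list alone), and the glucocorticoid-responsive Fkbp5 -0.57 (SE 0.11, adjusted p = 0.179 and 0.00354). Adjustment over a list alone does not correct for the number of lists. The neutrophil marker Il1r2 also passed that way (0.51, SE 0.13, edgeR adjusted p = 0.0342 over its list alone and 0.509 over all genes). Akr1c18, Penk and Fkbp5 were called over all genes by DESeq2 (adjusted p = 0.00894, 0.016 and 0.000344). None of them was called by limma-voom, with or without library weights. Interferon response genes varied within each sex: their score was 1.33 in female replicate 4 and 1.17 in male replicate 4, against -1.4 in female replicate 3.

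Splitting the 8 libraries into groups of 4 in all 35 ways gave as many called genes as the real split (14) in 2 of 35, the real one included. As many outside the sex-chromosome lists (8) also arose in 2 of 35, so the number of splits alone did not exclude chance for either count. The other such split called 1476 genes, with male replicates 1 and 4 and female replicates 2 and 3 on one side. Those are the 4 libraries with the lowest fast muscle scores, which points to muscle content as a structure of the samples. Of the other 34 splits 31 called 0 genes and 2 called 1. For gene lists 35 of 35 splits called at least as many as the real one (6), with 9 to 24 in the others, so the list calls with a preset correlation did not set the sexes apart from arbitrary groupings.

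The 8 called genes outside the sex-chromosome lists were set against muscle content and read sharing. With the muscle score as a covariate the median ratio of new to old log2 fold change was 0.99 (range 0.93 to 1.07) and 8 of 8 remained called. The score ran from 0.74 to 9.63 in females and from 5.03 to 10.08 in males. A gene that tracks it would vary within each sex and hardly be called, so the selection made such ratios likely. The values show only that the fold changes of these 8 genes did not depend on the score, and do not weigh against muscle content for other genes. Of the 7 genes with a counted paralog, 1 had a paralog moving the other way by a comparable CPM: Serpinb6a, at 205 ± 84.5 CPM in females and 225 ± 66.1 CPM in males. That difference lies within its spread. Reads shared with a paralog could also move both genes the same way, as Akr1c18 (70 ± 21 against 33.5 ± 7.12 CPM) moved with Akr1c21, so read sharing stays open. A difference between the sexes stays open as a biological explanation, which these libraries cannot separate from an effect of prolactin, since all mice received it.

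For the circadian clock list, the muscle covariate left the mean log2 fold change at 1 times its value. Without female replicate 3 the mean was 0.19, and 0.16 with the covariate in that fit (camera adjusted p = 0.0157), against 0.24 with all libraries. The list stayed called in each, but calls with a preset correlation did not set the sexes apart from arbitrary groupings and cannot weigh against muscle content. What the means show is narrower. The covariate did not lower the mean with all libraries, and lowered it from 0.19 to 0.16 without female replicate 3. A candidate explanation is a different time of day at collection. That would shift evening genes against morning genes, and they differed by 0.18 (SE 0.26, exact permutation p = 0.457, two-sided, smallest possible 0.029), too uncertain to exclude it. A sex difference in clock genes stays open as well.

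The lower fast muscle transcripts of females may rest on single libraries. The mean log2 fold change was -0.066 without female replicate 3 and 0.828 without male replicate 2. The difference in mean log2 CPM of these genes without male replicate 2, another measure, had a standard error of 2.11. By list score the female mean was -0.71, and male replicates 1, 3 and 4 had 0.44, 1.08 and -1.87. The value of 0.828 alone therefore does not show females higher without that library. Because the value with all libraries already met the bound set for the first of these tests, a single library with little muscle and lower muscle expression in females cannot be told apart here.

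Hypotheses formed on the genes with the smallest p-values were tested on the rest of each family. The 8 other Skint genes had a mean log2 fold change of 0.49, with 6 above 0 (limma camera p = 0.195 with an estimated correlation). Whether the family as a whole is higher in females, beyond Skint5 and Skint8 (1.60, SE 0.24, edgeR adjusted p = 0.106), stays open. Skint5 and Skint8 themselves were called by DESeq2 (adjusted p = 3.33e-09 and 7.96e-05). For Serpina3, where Serpina3a and Serpina3b lay above 0 and Serpina3m below, the 6 other members had a mean of -0.44 (p = 0.0536 with an estimated correlation), against the hypothesis of a family higher in females.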
